A study of Mus musculus with 12 samples.

How the data were processed

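RNA was sequenced in bulk from the femoral shafts of male mice that carried normal catalase genes (wild type) or lacked catalase (Cat knockout, Cat−/−). Catalase is the peroxisomal enzyme that breaks down hydrogen peroxide and can also oxidise ethanol. Per the labels, mice of 12 weeks were gavaged on 4 days in a row with ethanol at 3, 3, 4 and then 4.5 g per kg of body weight, taken from a solution of 31.5% ethanol by volume, or with an equal volume of phosphate-buffered saline (PBS). They were killed 6 hours after the last gavage. Marrow was spun out of the femurs, the shafts were stored in RNAlater, and RNA was extracted with Tri reagent. Each library held RNA pooled from 2 mice, and each of the 4 groups had 3 libraries, 12 in all. The p-values therefore measure the spread between pools, and the spread between single mice cannot be seen. No date or batch label was given in the sources used here.

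The deposited count table holds whole-number counts per Ensembl gene for 49315 genes, not normalized, per the file headers and the values themselves. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and the mouse genome build GRCm38. Their settings, the annotation release, the treatment of reads that map to several places and whether counting used strand are not given in the sources used here. Genes with near-identical copies (Cd59a and Cd59b, the osteocalcin genes Bglap, Bglap2 and Bglap3, the globin genes, Acot1) and genes with an overlapping or antisense partner (Irx3os) are therefore uncertain. A second deposited table holds a normalized signal, which is the count divided by 1 constant factor per library (the relative spread of the ratio was at most 9.88e-10), for the 17408 genes with a mean count above 10. This signal was used in 1 alternative only. Gene symbols came from the deposited normalized table for 17391 genes and otherwise from GENCODE M21 on GRCm38, which matched 48970 of the identifiers and gave the coordinates. Symbols shared by several identifiers (76) were left as identifiers.

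Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 18161, and libraries were scaled by TMM factors (0.908 to 1.05). Levels are given as CPM, the count of a gene scaled to the library total and these factors. One edgeR 4.0.16 quasi-likelihood model with robust estimation in R 4.3.3 held 1 coefficient per group (8 residual degrees of freedom, common dispersion 0.0338). It gave the ethanol effect in each genotype, the knockout effect under each gavage, their difference (the interaction) and both averaged effects. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over all tested genes). The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Every adjusted p of a single gene comes from this edgeR test unless another tool is named.

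Gene lists (42 lists, 709 symbols, 1 of them, Ahsp, without a match) covered bone, marrow and muscle cell types, signalling and stress pathways, ethanol, peroxide and lipid metabolism, and genes near Cat. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01 and adjustment over the lists. Counts of called members are given over all genes and adjusted over the list alone. Because camera's preset correlation is small, each list was tested again with an estimated correlation and with fry, a test of whether the members move 1 way.

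The genes named are those with an adjusted p under 0.05, a mean CPM of at least 1 and no overlap between the 3 libraries of each group. Of these, leaving out predicted genes, pseudogenes, and immunoglobulin and T cell receptor segments, the 12 with the largest rise and the 12 with the largest fall per comparison were taken (6 and 6 for the interaction). Up to 4 called members of each list with the largest change were added. Where a discussed list had no called member, up to 2 members with the smallest p are given as values. Cat was taken in every comparison, as were members of the lists of ethanol and of peroxide metabolism. The averaged effects have no such rule, and genes named there or elsewhere outside it are said to be chosen after their values were seen. Some genes that the rule takes are not reported here by name.

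The comparisons, tests, lists, this rule and the alternatives were fixed before the data were examined, except where said. The alternatives were RLE and upper-quartile factors, no low-count filter, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited normalized signal plus 1, a fit of only the 2 groups compared, an added threshold of 1 on the log2 fold change, the muscle list or the blood cell lists (erythroid, neutrophil and B cell) as a covariate, and leaving out each library in turn. DESeq2 adjusted over all genes, without its filter on mean counts, was added after the results were seen. List means were also compared by exact permutation of treatment within genotype, two-sided over 400 relabellings, for the interaction with the averaged ethanol effect taken out first. These permutations were added after the results were seen. A fit without the 3 libraries highest in muscle genes was added after the library composition was seen. It leaves 1 wild-type PBS library and 2 wild-type ethanol libraries, and the lone library is assumed to vary like the other groups.

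The pipeline was tested on simulated counts for 17960 genes, 200 of them changed in the wild-type ethanol group. The test of the ethanol effect in wild type recovered 28.4% of 67 genes changed 1.5-fold, 56.9% of 65 changed 2-fold and 93.8% of 65 changed 4-fold, and called 2 unchanged genes. For the interaction the shares were 2.99%, 36.9% and 81.5%, with 2 unchanged genes called. Genes were drawn independently, with the same dispersion per gene in all groups and no muscle component. The shares therefore need not hold for the real libraries.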

Results

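Gene expression was measured by bulk RNA sequencing in the femoral shaft, the cortical bone of the thigh, of male catalase knockout and wild-type mice after 4 days of binge ethanol or PBS gavage. The 4 groups were knockout with PBS (libraries 1 to 3), knockout with ethanol (libraries 4 to 6), wild type with PBS (libraries 7 to 9) and wild type with ethanol (libraries 10 to 12). Library totals ran from 19950222 counts (library 12) to 28789308 counts (library 2). Replicate libraries had correlations of log2 CPM across genes of 0.989 to 0.993 in the knockout and 0.959 to 0.988 in wild type. Every replicate pair differed by more than sampling noise, with a chi-square per gene of 9.42 to 30.1 in the knockout and 34.5 to 172 in wild type. The edgeR model shares its spread over all 4 groups, so counts of called genes are not directly comparable between genotypes.

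Cat itself was lower in every knockout library than in every wild-type library, but its transcript was still counted. Cat (ENSMUSG00000027187, chromosome 2, 103453849 to 103485160, GRCm38) had 152 ± 23.4 CPM (SD, n = 3) in wild type with PBS and 67.5 ± 2.22 CPM (n = 3) in the knockout with PBS. After ethanol the values were 160 ± 14.4 CPM and 71.6 ± 2.58 CPM (n = 3 each). The knockout difference was −1.17 on the log2 scale under PBS (SE 0.10, adjusted p = 0.0020), or 0.446-fold, and −1.16 under ethanol (SE 0.10, adjusted p = 0.0010). The knockout libraries held 1610 to 2001 Cat counts and the wild-type libraries 2742 to 3772. Which part of the gene the knockout allele removes is not given in the sources used here, so these counts check the genotype labels by level only. Ethanol did not detectably change Cat: the log2 difference was 0.083 (SE 0.10, adjusted p = 0.748) in wild type and 0.085 (SE 0.10, adjusted p = 0.771) in the knockout.

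The only other gene past the edgeR test between genotypes was Cd59a, which encodes a membrane protein that blocks the complement attack complex. Cd59a (ENSMUSG00000032679, chromosome 2, 104095801 to 104115354) lies near Cat and fell from 29.3 ± 5.75 to 10.2 ± 1.39 CPM under PBS, a log2 change of −1.53 (SE 0.15, adjusted p = 0.0024). Under ethanol it was 31.2 ± 2.54 CPM in wild type and 8.63 ± 0.68 CPM in the knockout, a log2 change of −1.85 (SE 0.15, adjusted p = 0.00069; n = 3 each, edgeR). In a fit of only the 6 PBS libraries Cd59a was at −1.54 and no longer passed (adjusted p = 0.0548), while Cat and the predicted genes Gm15564 and Gm42418, named after their values were seen, did. Its neighbouring copy Cd59b had 2.39 and 1.70 CPM in wild type and 1.16 and 1.29 CPM in the knockout (PBS and ethanol), with an averaged log2 difference of −0.72 (adjusted p = 0.328). Other neighbours, named here after their values were seen, were Elf5 (0.803 and 1.19 CPM in the knockout against 0.101 and 0.171 CPM in wild type, PBS and ethanol, averaged adjusted p = 0.0886) and Tcp11l1 (averaged log2 difference 0.67, adjusted p = 0.185). The averaged difference of Elf5 passed without library 11 or 12 (adjusted p = 0.0160 and 0.0143) and that of Tcp11l1 without library 7 (adjusted p = 0.0443). Of the fixed list of genes near Cat, 25 were tested, and 1 fell under PBS, with 3 higher and 2 lower when adjusted over the list alone.

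**Figure D1:**
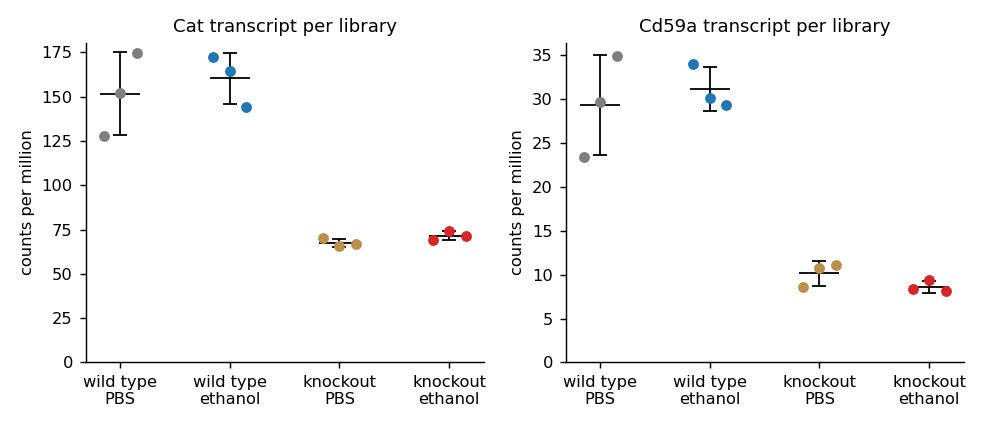
CPM of Cat and Cd59a in each of the 12 libraries by group. Points are libraries and the bar with its error is the mean ± SD of 3 libraries. Every knockout library lies below every wild-type library for both genes (Cat means 67.5 and 71.6 CPM against 152 and 160 CPM).

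The libraries also differed in how much muscle RNA they held, with the highest shares in 3 of the 6 wild-type libraries. The skeletal muscle list (myosins, troponins, creatine kinase) took 3.08% and 3.50% of the counts in wild-type PBS libraries 8 and 9 and 3.70% in wild-type ethanol library 12. It took 0.137% to 1.97% in the other wild-type libraries and 0.324% to 1.26% in the knockout. The first principal component of log2 CPM (42.0% of the variance) put libraries 8, 9 and 12 at scores of 46.9 to 52.6 and all others at −46.4 to 11.8. Mitochondrially encoded genes took 5.04% to 6.40% of the counts in those 3 libraries and 2.20% to 2.94% in the others. The second component (15.6%) held ethanol libraries at 11.02 to 30.7 and PBS libraries at −22.8 to −9.82. Marrow RNA remained in every shaft, with haemoglobin genes at 0.858% to 1.74% of counts and the neutrophil list at 2.38% to 4.25%.

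**Figure D2:**
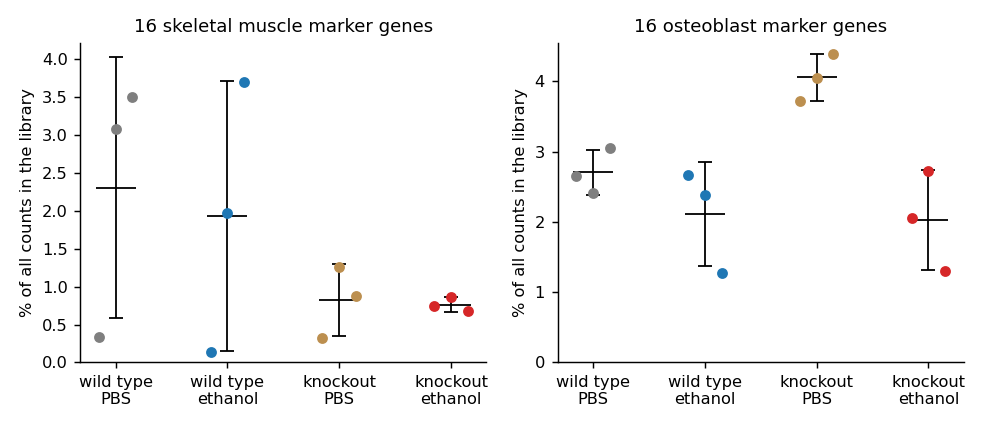
Percent of each library's counts on 16 skeletal muscle markers and on 16 osteoblast markers, for the 12 libraries by group. Libraries 8, 9 and 12, all wild type, have muscle shares of 3.08% to 3.70%, above the 9 others. The lowest osteoblast shares, 1.27% and 1.30%, are those of ethanol libraries 12 and 6.

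Under PBS, 19 lists differed between genotypes by camera while none of their members passed the gene test. The 16 muscle genes were all lower in the knockout (median log2 difference −1.61; for example Myh2 −2.75, SE 1.21, adjusted p = 0.605, and Mb −2.48, SE 1.11, adjusted p = 0.605). So were the 13 mitochondrially encoded genes (−1.01) and the 27 nuclear genes of oxidative phosphorylation (−0.50). The 13 erythroid genes were all higher (0.42), as were 27 of 28 cell cycle genes (0.16) and 10 of 10 platelet genes (0.23). B cell (0.26), monocyte and macrophage (0.23), osteoblast (0.29) and bone matrix (0.21) lists had higher medians. Neutrophil (−0.28), hypoxia (−0.25), osteocyte (−0.26), heat shock (−0.28), peroxisome (−0.11), cholesterol synthesis (−0.14), lipogenesis (−0.11), unfolded protein response (−0.068) and fatty acid oxidation (−0.36) lists had lower ones. The camera adjusted p ran from 2.0e-10 to 0.0461, and none of the 19 passed with an estimated correlation (adjusted p = 0.649 to 0.726). Without libraries 8, 9 and 12, which left 1 wild-type PBS library, 7 of the 19 medians turned: muscle (1.35), mitochondrially encoded (0.15), oxidative phosphorylation (0.16), fatty acid oxidation (0.13), heat shock (0.15), lipogenesis (0.040) and platelet (−0.024). With the muscle list as a covariate, 14 of the 18 other lists kept their camera call, and the osteocyte, B cell, heat shock and lipogenesis lists lost it (adjusted p = 0.125, 0.210, 0.712 and 0.582).

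Single libraries decided 13 of these 19 calls. Without library 7 the osteoblast (median 0.25), osteocyte (−0.14), neutrophil (−0.30), B cell (0.25), unfolded protein response (−0.078) and cholesterol (−0.12) lists lost their call. Without library 8 the muscle (−1.28), neutrophil (−0.079), B cell (0.16), platelet (0.13), peroxisome (−0.042), fatty acid oxidation (−0.28), heat shock (−0.23) and lipogenesis (−0.076) lists lost theirs. Without library 9 it was the osteocyte (−0.24), muscle (−1.18), macrophage (0.23), fatty acid oxidation (−0.26), unfolded protein response (−0.053), heat shock (−0.071) and lipogenesis (−0.16) lists. Without library 1 the osteocyte (−0.21), muscle (−1.22), B cell (0.23), unfolded protein response (−0.050), heat shock (−0.25) and lipogenesis (−0.13) lists lost theirs, and without library 3 the osteocyte (−0.24) and lipogenesis (−0.15) lists. Other medians moved by over 1.5 times with the call kept: without library 8 hypoxia (−0.16), oxidative phosphorylation (−0.32), mitochondrially encoded (−0.65) and cholesterol (−0.088), without library 9 neutrophil (−0.46), B cell (0.45), bone matrix (0.31) and cholesterol (−0.25), and without library 7 platelet (0.39), fatty acid oxidation (−0.55), heat shock (−0.43) and lipogenesis (−0.17).

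Under ethanol, 11 lists differed between genotypes by camera, again with no member called but Cat and Cd59a in any list. All 28 cell cycle genes were higher in the knockout (median 0.23), all 13 erythroid genes (0.36) and all 10 platelet genes (0.27). The integrated stress response list, the genes driven by the factor ATF4 when amino acids or protein folding fail, had a median of 0.31. Its members with the smallest p were Slc7a5 (0.71, SE 0.12, adjusted p = 0.324, and 0.0370 without a low-count filter) and Slc3a2 (0.44, SE 0.073, adjusted p = 0.342), which together form an amino acid transporter, and 10 of 18 members were higher when adjusted over the list alone against 0 over all genes. Osteoclast genes were lower (13 of 14, median −0.33), as were oxidative phosphorylation (−0.24), mitochondrially encoded (−0.59), peroxisome (−0.085), neutrophil (−0.20), NADPH oxidase (−0.20) and osteoblast (−0.14) lists. None of the 11 passed with an estimated correlation (adjusted p = 0.239 to 0.966), and with the muscle list as a covariate the neutrophil and NADPH oxidase lists lost their camera call (adjusted p = 0.0508 and 0.0602). Without library 12 the neutrophil (−0.029), platelet (0.16), NADPH oxidase (−0.069), peroxisome (−0.035), oxidative phosphorylation (−0.022) and mitochondrially encoded (−0.10) lists lost it too, and the erythroid and cell cycle medians were 0.17 and 0.15 with the call kept. The osteoblast median turned to 0.083 without library 6 and was −0.010 and −0.067 without library 10 or 11, each without a call, and −0.39 and −0.31 without library 5 or 12. Calls were also lost without library 6 for the platelet (0.14) and NADPH oxidase (−0.19) lists and without library 5 for the neutrophil list (−0.19). The osteoclast and oxidative phosphorylation medians were −0.14 and −0.37 without library 10 and the neutrophil median −0.33 without library 11.

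By edgeR, 2 genes fell and 0 rose in the knockout under each gavage, while 1350 genes under PBS and 1050 under ethanol had an unadjusted p under 0.05 against 908.1 expected by chance. Genes of the same libraries are not independent, so these counts do not measure an excess of knockout effects. DESeq2 called 2 under PBS and 14 under ethanol, and limma-voom 2 under each. The knockout effects under PBS and under ethanol, which share no library, had a Pearson r of 0.551 and a Spearman rho of 0.432 across 18161 genes, which are not independent replicates. That r was 0.0941 without library 12, 0.171 with the muscle list as a covariate and −0.0880 without the 3 high-muscle libraries.

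Ethanol changed 229 of 18161 genes in the wild-type shaft. Of these 101 rose and 128 fell, 26 and 24 of them by at least 2-fold. The calcitonin receptor Calcr, a marker of mature osteoclasts, rose from 1.41 ± 0.35 to 7.10 ± 0.25 CPM (log2 change 2.33, SE 0.30, adjusted p = 0.0109). Calca, which encodes calcitonin and the neuropeptide CGRP, rose by 2.98 (SE 0.53, adjusted p = 0.0298) from a low 0.251 ± 0.138 CPM to 2.06 ± 1.33 CPM. The metal-binding metallothioneins Mt2 and Mt1 rose by 1.73 (SE 0.24, adjusted p = 0.0219) and 1.01 (SE 0.13, adjusted p = 0.0109), Mt2 from 15.9 ± 3.57 to 52.9 ± 8.93 CPM. Cyp26b1, which degrades retinoic acid, rose by 1.72 (SE 0.27, adjusted p = 0.0251). Also among the 12 largest rises were Rasl10b, Kcnt1, Acot1, Abca6, Zfp811, Msc and Il9r, with log2 changes of 1.16 to 2.43.

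Among the falls in wild type, the atypical cadherin Fat3 fell from 37.0 ± 2.86 to 10.54 ± 2.20 CPM (log2 change −1.81, SE 0.20, adjusted p = 0.0094). The matrix protease Adamts18 fell from 7.78 ± 2.01 to 1.69 ± 0.42 CPM (−2.19, SE 0.28, adjusted p = 0.0109). Rspo2, a secreted enhancer of Wnt signalling, fell by 1.47 on the log2 scale (SE 0.29, adjusted p = 0.0395). Panx3, a pannexin channel of osteoblasts and chondrocytes, changed by −1.16 (SE 0.23, adjusted p = 0.0398). The noradrenaline transporter Slc6a2 changed by −1.68 (SE 0.35, adjusted p = 0.0449), and Bcan, Gng4, Mettl21b, Fam131b, Flrt3, Rnft2 and Irx3os by −1.95 to −1.21.

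Genes of the cholesterol synthesis list formed the clearest group in wild type by camera and by called members. By fry and with an estimated correlation the unfolded protein response list was ahead of it. Of 19 cholesterol genes 9 fell and 0 rose, and 13 fell when adjusted over the list alone. The synthesis enzymes Cyp51 (−0.73, SE 0.11, adjusted p = 0.0227) and Sqle (−0.64, SE 0.086, adjusted p = 0.0109) and the sterol sensor partner Insig1 (−0.62, SE 0.10, adjusted p = 0.0242) were among those that fell. The list median was −0.44 (camera adjusted p = 1.1e-11), with adjusted p = 0.437 with an estimated correlation and 0.0075 by fry, which passed 2 of the 13 lists camera called in wild type, this one and the unfolded protein response list (0.0028). The lipogenesis list was not called (median −0.14, camera adjusted p = 0.110), though its regulator Srebf1 fell by 0.28 (adjusted p = 0.0361).

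Glucocorticoid response genes were higher in wild type: 18 of 19 were above PBS (median 0.69), 3 rose over all genes (Mt2, Mt1 and Errfi1, the last by 0.88, SE 0.11, adjusted p = 0.0109), and 6 rose when adjusted over the list alone. Camera gave adjusted p = 3.8e-07, and adjusted p = 0.830 with an estimated correlation, and the median was 0.38 without library 7. All 14 osteoclast genes were higher (median 0.33), 1 of them called over all genes (Calcr) and 10 when adjusted over the list alone. Ctsk, the main collagen-degrading protease of osteoclasts, had 0.71 (SE 0.18, adjusted p = 0.0838). Camera gave adjusted p = 3.3e-08 for this list, and adjusted p = 0.681 with an estimated correlation. Tnfsf11 (RANKL), the osteoclast-inducing cytokine, rose by 0.84 (SE 0.17, adjusted p = 0.0398), while the list of osteoclastogenesis regulators it belongs to did not move as a group (camera adjusted p = 0.914).

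All 16 osteoblast genes were lower in wild type (median −0.56), with 0 called over all genes and 2 when adjusted over the list alone: Phospho1, a mineralisation phosphatase, at −0.52 (SE 0.14, adjusted p = 0.0920) and the parathyroid hormone receptor Pth1r at −0.55 (SE 0.15, adjusted p = 0.109). Camera gave adjusted p = 1.5e-05, and adjusted p = 0.830 with an estimated correlation. The osteoblast list mean was 7.32 to 7.61 log2 CPM in the PBS libraries. After ethanol it was 7.09, 7.01 and 6.43 in libraries 10, 11 and 12, so library 12 carried much of the fall. Of 27 bone matrix and collagen processing genes, 22 were lower (median −0.39), yet the collagenase Mmp13 rose from 292 ± 44.1 to 582 ± 92.4 CPM (0.99, SE 0.17, adjusted p = 0.0298), and Crtap, a collagen prolyl-hydroxylation partner, fell (−0.47, SE 0.10, adjusted p = 0.0489); 2 rose and 3 fell when adjusted over the list alone. Of 14 osteocyte genes, 13 were lower (median −0.42), led by Phex (−0.74, SE 0.19, adjusted p = 0.101), the 1 member that fell when adjusted over the list alone. Of 18 chaperones and other unfolded protein response genes, 16 were lower (median −0.17), 2 fell (Hyou1 −0.41, SE 0.069, adjusted p = 0.0254, and Sdf2l1 −0.41, SE 0.072, adjusted p = 0.0298) and 10 fell when adjusted over the list alone. Camera called these 3 lists at adjusted p = 0.0042, 0.0062 and 1.0e-05, and adjusted p with an estimated correlation was 0.957, 0.957 and 0.341. The bone matrix call was lost without library 9 (median −0.23, adjusted p = 0.0578), without library 12 (−0.16, adjusted p = 0.109) and without the 3 high-muscle libraries (−0.060, adjusted p = 0.506). The osteocyte call was lost without library 7 (−0.36, adjusted p = 0.0877) or 10 (−0.33, adjusted p = 0.0620).

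Camera also called oxidative phosphorylation (median −0.32), mitochondrially encoded (−0.58) and hypoxia (−0.27) lists as lower and monocyte and macrophage (0.11), autophagy and FoxO (0.16) and T and NK cell (0.18) lists as higher in wild type, with adjusted p = 0.830 to 0.957 with an estimated correlation. Without libraries 8, 9 and 12 the medians of the first 2 turned to 0.13 and 0.15, and with the muscle list as a covariate the mitochondrially encoded, macrophage and T and NK lists lost their call (adjusted p = 0.0632, 0.0651 and 0.0768). All 6 calls depended on single libraries. The oxidative phosphorylation call was lost without library 8, 9 or 10 (medians −0.15, −0.20 and −0.20), and the median was −0.55 and −0.52 without library 7 or 12. The mitochondrially encoded call was lost without library 8, 9, 10 or 11 (−0.23, −0.42, −0.27 and −0.48), against −0.89 and −1.0 without library 7 or 12. The hypoxia call was lost without library 8 or 10 (−0.12 and −0.17), against −0.42 and −0.47 without library 7 or 12. The macrophage call was lost without library 9, 10 or 11 (0.12, 0.073 and 0.061), against 0.18, 0.19 and 0.25 without library 7, 8 or 12. The autophagy and FoxO call was lost without library 7 or 12 (0.092 and 0.11), and the T and NK call without library 8, 10 or 11 (0.11, 0.038 and 0.14), against 0.39 without library 12.

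Members of these lists past the test over all genes in wild type were Ankrd37 (−1.03, adjusted p = 0.0381) of the hypoxia list, Cd14 (1.12, adjusted p = 0.0109) of the macrophage list and Gzma (0.98, adjusted p = 0.0310) of the T and NK list, with 4 lower, 1 higher and 3 higher in these lists when adjusted over the list alone and 2 higher in the autophagy and FoxO list. The 229 calls depended on replication and on the other groups in the model: 320 genes were called without library 7, 143 of them among the 229, and 45, 40, 35, 46 and 136 without library 8, 9, 10, 11 or 12. There were 37 without the 3 high-muscle libraries, 20 of them among the 229. A fit of only these 6 libraries called 4 genes (Errfi1, Calcr, Fat3 and an immunoglobulin segment, Ighv9-1, named after their values were seen), DESeq2 called 731 and limma-voom 138. With upper-quartile factors the balance of directions turned, with 111 genes up and 75 down against 101 and 128.

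In catalase knockout mice ethanol changed 339 genes, 175 up and 164 down, 43 and 53 of them by at least 2-fold. Trib3, a pseudokinase induced by ATF4, rose from 1.49 ± 0.39 to 12.1 ± 3.96 CPM (log2 change 3.02, SE 0.33, adjusted p = 0.0036). Calca rose by 3.69 (SE 0.55, adjusted p = 0.0094), Mt2 from 18.99 ± 5.55 to 75.3 ± 10.3 CPM (1.99, SE 0.24, adjusted p = 0.0058) and Erfe, the erythroid hormone that lowers hepcidin, by 2.60 (SE 0.47, adjusted p = 0.0262). Il1r2, the decoy receptor for interleukin 1, rose by 1.74 (SE 0.30, adjusted p = 0.0243). Rasl10b, Fam107a, Ms4a8a, Kcnt1, Cyp26b1 and Vipr2 were also among the 12 largest rises, with the highest at 3.14.

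The falls in the knockout were led by Slc6a2 (log2 change −2.67, SE 0.35, adjusted p = 0.0056) and Mettl21b (−2.43, SE 0.29, adjusted p = 0.0038). Fat3 fell from 46.9 ± 6.09 to 11.4 ± 3.08 CPM (−2.04, SE 0.20, adjusted p = 0.0030) and Panx3 from 6.51 ± 0.19 to 1.62 ± 0.29 CPM (−2.01, SE 0.23, adjusted p = 0.0036). Cemip, which depolymerises hyaluronan, changed by −1.90 (SE 0.26, adjusted p = 0.0072) and Rspo2 by −1.84 (SE 0.29, adjusted p = 0.0113). Pcdhac2, Hapln4, Bcan, Adamts18, Xcl1 and Gng4 fell by 1.69 to 2.34 on the log2 scale.

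Osteoblast genes were lower as a group in the knockout: all 16 had lower values after ethanol (median −0.98), 4 fell over all genes and 15 when adjusted over the list alone. The 4 were Bglap3, an osteocalcin gene at under 1 CPM (−2.02, SE 0.37, adjusted p = 0.0224), Phospho1 (−0.78, SE 0.14, adjusted p = 0.0200), Pth1r (−0.70, SE 0.15, adjusted p = 0.0430) and the osteoblast transcription factor Runx2 (112 ± 4.73 to 85.5 ± 5.08 CPM; −0.39, SE 0.077, adjusted p = 0.0270). Camera gave adjusted p = 8.0e-14 for the list, with adjusted p = 0.411 with an estimated correlation and 0.0199 by fry. The bone matrix and collagen processing list had 25 of 27 genes lower (median −0.57), 2 fell (Crtap −0.48, SE 0.10, adjusted p = 0.0344, and P4ha1 −0.63, SE 0.14, adjusted p = 0.0435) and 1 rose (Mmp13 0.80, SE 0.17, adjusted p = 0.0430), with 18 and 2 when adjusted over the list alone. Its camera adjusted p was 3.1e-10, and adjusted p = 0.571 with an estimated correlation. The osteocyte list was lower (11 of 14, median −0.35, camera adjusted p = 0.0157) with no member called, Phex at −0.66 (SE 0.19, adjusted p = 0.114), and adjusted p = 0.975 with an estimated correlation. Its call was lost without library 2 (median −0.28) or 6 (−0.14), and the median was −0.58 without library 5. Library 6 had the lowest mean log2 CPM of all libraries for the osteoblast (6.26), osteocyte (5.51), bone matrix (7.14), chondrocyte (0.973) and tendon and periosteal fibroblast (4.29) lists. The osteoblast means of libraries 4 and 5 (6.76 and 7.02) were also below those of the knockout PBS libraries (7.59 to 7.86).

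The integrated stress response list was higher in the knockout after ethanol: 8 of 18 genes rose over all genes and 9 when adjusted over the list alone, with 1 lower by that count (median 0.46). Trib3 led, followed by the asparagine synthetase Asns (42.0 ± 2.68 to 101 ± 10.6 CPM; 1.27, SE 0.14, adjusted p = 0.0036), the amino acid transporter subunit Slc7a5 (0.91, SE 0.12, adjusted p = 0.0054) and the folate enzyme Mthfd2 (0.84, SE 0.12, adjusted p = 0.0075). Camera gave adjusted p = 2.3e-07, with adjusted p = 0.411 with an estimated correlation and 0.0039 by fry, which passed only this list and the osteoblast list of the 10 that camera called in the knockout. Glucocorticoid response genes were higher in 19 of 19 (median 0.75), and 5 rose over all genes and 8 when adjusted over the list alone, among them Fkbp5, a co-chaperone of the glucocorticoid receptor (76.5 ± 6.59 to 210 ± 44.8 CPM; 1.46, SE 0.30, adjusted p = 0.0433), Hif3a (1.15, adjusted p = 0.0411) and Mt1 (1.15, adjusted p = 0.0036). Camera gave adjusted p = 1.0e-09, and adjusted p = 0.565 with an estimated correlation.

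In the cholesterol list 3 genes fell in the knockout, Cyp51 (−0.61, SE 0.11, adjusted p = 0.0226), Insig1 (−0.54, SE 0.10, adjusted p = 0.0234) and Hmgcs1 (−0.49, SE 0.091, adjusted p = 0.0226), and 11 when adjusted over the list alone (median −0.31, camera adjusted p = 7.0e-07, and adjusted p = 0.565 with an estimated correlation). Among fatty acid oxidation genes 3 rose, with Acot1 (1.28) and the lipid droplet protein Plin2 (0.57, SE 0.12, adjusted p = 0.0369) among them, and 5 rose when adjusted over the list alone. Of the immediate early genes 4 rose and 1 fell, by both counts, with Egr1 (0.62, SE 0.096, adjusted p = 0.0113), Fos (0.62) and Ier2 (0.40) up and Nr4a2 (−0.82, adjusted p = 0.0399) down. The Wnt list (median −0.18, Rspo2 the 1 gene that fell) was lower, and the autophagy and FoxO list (median 0.19, Gabarapl1 0.50, adjusted p = 0.0300) was higher. Camera gave these last 4 lists adjusted p = 0.0157, 0.0303, 0.0049 and 0.0074, and adjusted p with an estimated correlation was 0.975, 0.565, 0.779 and 0.565. Without library 1 the fatty acid oxidation (median 0.070 against 0.099) and immediate early (0.14 against 0.16) calls were lost, and without library 6 the Wnt call (−0.12). Without library 2 the fatty acid oxidation and Wnt medians were 0.16 and −0.28, and without library 4 the Wnt median was −0.29.

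In the knockout, Calcr rose (1.61, SE 0.29, adjusted p = 0.0200), but the osteoclast list did not pass (median 0.077, camera adjusted p = 0.120). Pparg, the main adipocyte transcription factor, fell by 0.81 (SE 0.15, adjusted p = 0.0226). The unfolded protein response list (median −0.081, camera adjusted p = 0.0859) and the chondrocyte list (−0.57, camera adjusted p = 0.0608) were not called. Leaving out library 1, 2, 3, 4, 5 or 6 left 67, 52, 58, 158, 217 and 71 calls. A fit of only these 6 libraries called 1677, 319 of them among the 339, and DESeq2 called 986.

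The lists closest to catalase chemistry did not move as groups with ethanol in either genotype. Of 18 genes for removal of hydrogen peroxide and superoxide, 0 were called in wild type, where Prdx1 was at −0.20 (SE 0.055, adjusted p = 0.103) and Gpx3 at 0.48 (SE 0.14, adjusted p = 0.111). In the knockout 1 fell, the peroxiredoxin Prdx1 (190 ± 4.49 to 160 ± 0.65 CPM; −0.25, SE 0.055, adjusted p = 0.0430); adjusted over the list alone, 1 rose and 1 fell in wild type and 3 fell in the knockout. Of 15 genes of ethanol and aldehyde metabolism 0 were called in either genotype by edgeR, and adjusted over the list alone 0 in wild type, and 3 higher and 1 lower in the knockout. The acetate-activating enzyme Acss3 was at 0.74 (SE 0.22, adjusted p = 0.132) and 0.97 (SE 0.22, adjusted p = 0.0513), and Aldh2, the main acetaldehyde dehydrogenase, at 0.024 (SE 0.11, adjusted p = 0.944) and 0.097 (SE 0.11, adjusted p = 0.764). Camera adjusted p in wild type and knockout was 0.311 and 0.541 for peroxide removal, 0.311 and 0.103 for ethanol metabolism, 0.862 and 0.871 for NRF2 targets and glutathione, 0.341 and 0.620 for NADPH oxidases, and 0.510 and 0.245 for peroxisome genes. Hmox1, an NRF2 target that degrades haem, had −0.59 (SE 0.22, adjusted p = 0.220) and −0.71 (SE 0.22, adjusted p = 0.132).

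Other lists not called for ethanol in either genotype, with camera adjusted p in wild type and knockout, were skeletal muscle (0.290 and 0.979), cell cycle (0.0663 and 0.979), heat shock (0.123 and 0.979), megakaryocyte and platelet (0.332 and 0.361), endothelial (0.338 and 0.891), erythroid (0.777 and 0.923), B cell (0.914 and 0.245) and neutrophil (0.165 and 0.0593). The remaining ones were mast cell and basophil (0.866 and 0.979), interferon response (0.500 and 0.198), NF-kB and acute inflammation (0.862 and 0.979), p53 targets (0.914 and 0.574), circadian clock (0.862 and 0.979), tendon and periosteal fibroblast (0.777 and 0.245), marrow stromal and adipose (0.777 and 0.979), TGF-beta, BMP and IGF signalling (0.914 and 0.979) and genes near Cat (0.545 and 0.620). Adjusted over the list alone, at most 4 members of any of these lists passed in a genotype. Single members passed over all genes, such as Ctgf (0.86 in wild type, adjusted p = 0.0398, and 1.25 in the knockout, adjusted p = 0.0072), Igfbp3 (0.63 in the knockout, adjusted p = 0.0343), Birc3 (0.46 and 0.52, adjusted p = 0.0489 and 0.0248), Socs3 (0.71 in the knockout, adjusted p = 0.0258) and Nat10 (−0.47 in wild type, adjusted p = 0.0468).

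**Figure D3:**
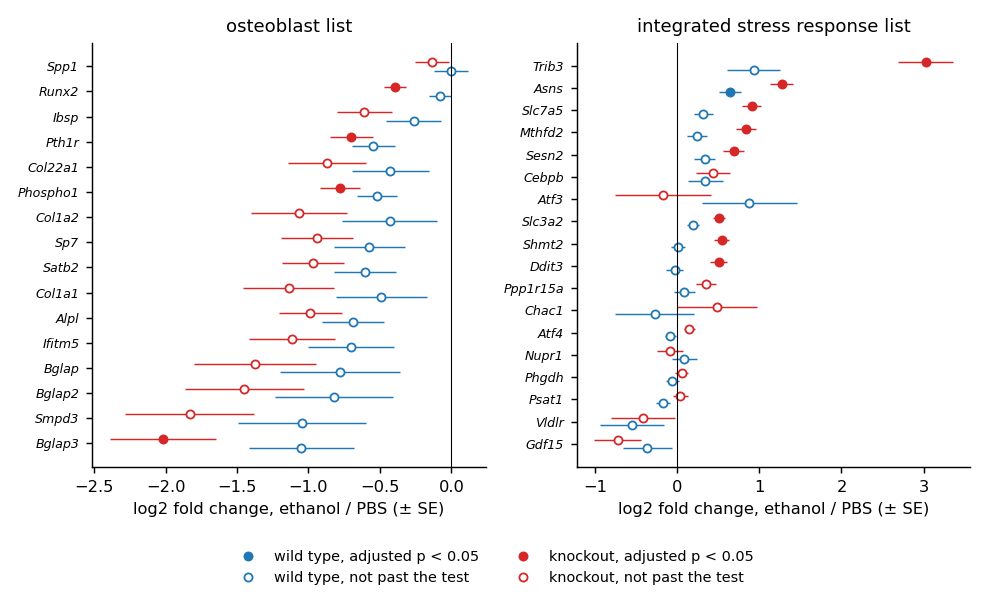
Log2 fold change (ethanol against PBS) ± SE of each member of the osteoblast and integrated stress response lists in wild-type and knockout mice, from the edgeR fit. Filled points have an adjusted p under 0.05: 0 and 4 osteoblast genes and 1 and 8 integrated stress response genes in wild type and knockout.

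Whether catalase alters the response to ethanol was asked with the interaction, and no gene passed. The edgeR test called 0 of 18161 genes, with 359 at an unadjusted p under 0.05 against 908.1 expected by chance and a smallest adjusted p of 1. Genes of the same libraries are not independent, so the low count does not measure a lack of interaction. DESeq2 called 1, an immunoglobulin segment (Igkv6-25, log2 difference 1.93, adjusted p = 0.0364, named after its value was seen), and limma-voom and limma-trend 0. Trib3 had the difference of 2.09 (SE 0.45) and the serine enzyme Shmt2 0.53 (SE 0.13), each with an adjusted p of 1 over all genes and 0.0105 when adjusted over the integrated stress response list alone, where 7 of 18 members passed. For Runx2 the difference was −0.31 (SE 0.11, adjusted p = 0.223 over the osteoblast list alone), and Cat had 0.0019 (SE 0.14). In simulated data the same test recovered 2.99% of 1.5-fold differences, 36.9% of 2-fold and 81.5% of 4-fold differences. Those data had independent genes, the same spread in every group and no muscle component. The shares are therefore not the power of the test in these libraries, and 0 calls do not show that the responses are equal.

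The ethanol effects in wild type and knockout had the same direction for most called genes. Among genes called in either genotype, 444 of 451 had the same sign in both, 59 rose in both against 0.973 expected for independent lists, 58 fell in both against 1.16 expected, and 0 were called in opposite directions. Both lists come from 1 model that shares the spread of each gene. Genes of low spread may thus enter both, and the expected numbers may be too low. Across 18161 genes, which are not independent replicates, the Pearson r was 0.486 and the Spearman rho 0.558, and these comparisons share no library. The r was 0.274 without the 3 high-muscle libraries and 0.650 for genes of at least 5 CPM in 3 libraries.

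**Figure D4:**
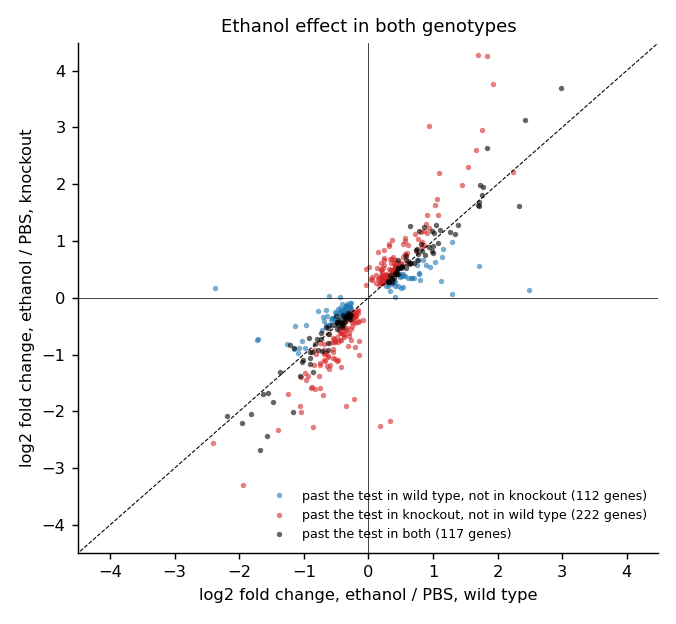
Log2 fold change of ethanol against PBS in wild type (horizontal) and in the knockout (vertical) for the genes past the test in wild type and not in the knockout (112), in the knockout and not in wild type (222) or in both (117). The dashed line marks equal changes, and 444 of the 451 genes have the same sign on both axes.

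With both genotypes averaged, ethanol changed 1967 genes, 912 up and 1055 down, 69 and 77 by at least 2-fold. Osteoblast genes fell in 11 of 16 cases and 15 when adjusted over the list alone (median −0.77), with Phospho1 at −0.65 (SE 0.098, adjusted p = 0.0028), Pth1r at −0.62 (SE 0.11, adjusted p = 0.0056) and Col1a1, the main bone collagen gene, at −0.81 (SE 0.22, adjusted p = 0.0476). Cholesterol genes fell in 12 of 19 (14 adjusted over the list alone) and bone matrix genes in 10 of 27 with 2 rising (20 and 2). Glucocorticoid response genes rose in 8 of 19 (9), integrated stress response genes in 7 of 18 (9, and 1 lower), osteoclast genes in 3 of 14 (8) and autophagy and FoxO genes in 4 of 16. Unfolded protein response genes fell in 6 of 18 (11) and osteocyte genes in 2 of 14 (9, and 1 higher). Genes in this comparison were named after their values were seen. None of the 14 lists that camera called held with an estimated correlation (smallest adjusted p = 0.467). Without library 1, 2, 3 or 6 the count was 1208, 1060, 1040 or 1194. With both gavages averaged, the knockout effect again called Cat and Cd59a only by edgeR, with 2591 genes at an unadjusted p under 0.05, and limma-voom called 2. DESeq2 called 215, but its filter on mean counts left 13028 genes without an adjusted p, Cd59a among them (log2 difference −1.69, unadjusted p = 8.8e-51). Adjusted over all genes, DESeq2 called 78, with Cat and Cd59a among them.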

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

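Of the tests in this part, the counts of genes and of lists in other splits of the libraries were planned, except for the interaction, and the splits for the interaction, the splits of list medians, the exact permutations and all other tests of explanations were chosen after the results were seen.

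For 11 lists the ethanol effect differed between genotypes by camera on the interaction, with no member called over all genes in any of them and none of the 11 past the test with an estimated correlation (smallest adjusted p = 0.268). The integrated stress response list had a median difference (knockout minus wild type) of 0.29 (camera adjusted p = 8.5e-09), from 0.087 in wild type and 0.46 in the knockout. The osteoblast list differed by −0.39 (5.6e-07), from −0.56 and −0.98. The osteoclast list differed by −0.37 (5.6e-07), from 0.33 and 0.077. The bone matrix list differed by −0.21 (2.2e-06), the unfolded protein response list by 0.12 (0.00043) and the cholesterol list by 0.12 (0.0012). The oxidative phosphorylation list differed by 0.27 (0.0051), the cell cycle list by 0.061 (0.0140) and the hypoxia list by 0.16 (0.0223). The tendon and periosteal fibroblast list differed by −0.23 (0.0414) and the heat shock list by 0.18 (0.0447). With the muscle list as a covariate the oxidative phosphorylation, hypoxia and heat shock lists lost their call (adjusted p = 0.0938, 0.0938 and 0.605). Without the 3 high-muscle libraries the oxidative phosphorylation and heat shock medians reversed (−0.19 and −0.096), and the unfolded protein response (0.051), hypoxia (0.091) and cell cycle (0.041) lists lost their call.

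Of these 11 calls, 7 were lost without single libraries. The oxidative phosphorylation call was lost without library 1, 8, 9, 10 or 11 (medians 0.079 to 0.23), and the median was 0.50 and 0.44 without library 7 or 12. The cell cycle median reversed without library 12 (−0.026), its call was lost without library 2, 4, 6 or 7 (0.026 to 0.054), and the median was 0.11, 0.11 and 0.15 without library 1, 5 or 10. The hypoxia call was lost without library 1, 5, 8, 9, 10 or 11 (0.059 to 0.17), against 0.27 without library 12. The tendon median turned to 0.032 without library 6, its call was lost without library 2, 3, 7, 8, 11 or 12 (−0.29 to −0.035), and the median was −0.47, −0.55 and −0.45 without library 4, 9 or 10. The heat shock call was lost without library 1, 2, 4, 8, 9 or 10 (0.037 to 0.18), against 0.35 and 0.12 without library 7 or 11. The bone matrix call was lost without library 6 (−0.097), with medians of −0.35, −0.35, −0.14 and −0.35 without library 5, 9, 10 or 12. The cholesterol call was lost without library 7 (0.055), with medians of 0.18, 0.081, 0.21 and 0.20 without library 5, 8, 9 or 12. Calls were kept with medians of −0.65, −0.26 and −0.59 for the osteoblast list without library 5, 6 or 12 and −0.12 for the osteoclast list without library 10.

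With the averaged ethanol effect taken out first, since relabelling would turn it into an interaction, other splits of the libraries gave at least 11 lists in 70 of 100 draws (at most 26), so chance cannot be excluded for this number of lists.

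The larger rise of integrated stress response genes in knockout mice was weighed as the first pattern. Muscle in the samples is argued against as the whole cause by size only, since the median difference was 0.33 with the muscle list as a covariate. Camera's adjusted p there (8.2e-08) adds no support, since camera called at least 11 lists in 70 of 100 splits. A part for muscle stays open, since the difference went from 0.29 to 0.14 without the 3 high-muscle libraries, a fit with 1 wild-type PBS library. Chance stays open too: with the averaged ethanol effect taken out first, 4 of 100 splits gave a median as far from 0 as 0.286 (the highest other 0.291), but the list was picked from 42 after its value was seen and did not pass by exact permutation (p = 0.015, and 0.315 when adjusted over the 42 lists), by fry (adjusted p = 0.160) or with an estimated correlation (adjusted p = 0.268). A stronger response to ethanol without catalase, the biological explanation the design offers, stays open and may be followed up through Trib3 and Shmt2. Neither gene passed over all genes. Both passed when adjusted over the list alone, but the list was picked after its value was seen, so this is not separate support.

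The lower osteoblast genes after ethanol were weighed as the second pattern, with a median of −0.77 over both genotypes. Chance is argued against by relabelling treatment within genotype. Only the real one of 100 splits reached that median (next −0.69), and the list mean passed by exact permutation (adjusted p = 0.035 over the 42 lists). Both use the same kind of relabelling, so they are not separate supports. By camera with an estimated correlation the list did not pass. Muscle is argued against as the cause, since the median was −0.79 with the muscle covariate. With it 13 of 16 members were called against 11, but calls over all genes also went from 1967 to 2753, so this count adds no support. Over both genotypes osteoblast genes went down beyond osteocyte genes by −0.49 on the log2 scale (exact permutation within genotype, two-sided p = 0.040, 400 relabellings). In the knockout the osteoblast minus osteocyte difference was 0.695 to 0.753 after ethanol against 1.39 to 1.64 under PBS. Wild-type PBS libraries had 0.821 to 1.07, so the larger fall in the knockout began from a higher PBS level. The mean osteoblast list share was 4.05% in the knockout and 2.70% in wild type under PBS. After ethanol it was 2.025% and 2.11%. Within the knockout, the osteoblast minus osteocyte differences argue against a smaller share of bone in the sample as the whole cause, if the osteocyte list tracks bone, which was not tested. In wild type the ranges overlapped and the shift rested on library 12 (0.126), so a smaller bone share stays open there. An effect of ethanol on osteoblasts remains a hypothesis.

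The lower Cd59a beside Cat was weighed as the third pattern. Reads shared with Cd59b are argued against, since the summed level of both genes was lower in all 6 knockout libraries than in all 6 wild-type libraries (difference −21.7 CPM). Muscle is argued against, since the averaged log2 difference was −1.66 with the muscle covariate (adjusted p = 3.8e-05, edgeR; −1.69 without it). DNA linked to the targeted allele remains a candidate explanation: of 43 other genes within 5 Mb of Cat, 32.6% had an unadjusted p under 0.05 for the averaged knockout effect against 14.2% of 18071 genes elsewhere (odds ratio 2.91, Fisher's exact test, two-sided p = 0.0019), 7 higher and 7 lower. The Fisher test counts genes of the same 12 libraries as independent, which they are not. The share elsewhere was itself above 0.05, and values of some neighbours had been seen before. This p is therefore only a rough guide. An effect of lost catalase on Cd59a was not tested apart from this and stays open.

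Other splits were counted for every comparison. For genes called in single comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05, and the real count and the highest of the others were 229 and 1477 for ethanol in wild type (2 splits as large), 339 and 0 for ethanol in the knockout (1 split), 2 and 0 for the knockout under PBS (1 split) and 2 and 4 under ethanol (2 splits). The split with 1477 genes set wild-type libraries 7, 10 and 11 against 8, 9 and 12 and so points to the muscle share as a structure of the samples. Chance is argued against for the averaged ethanol effect, since only the real one of 100 splits reached 1967 genes (next 600). For the averaged knockout effect another split reached the real count (2 genes, highest other 2, 2 of 100). Cat, 1 of the 2 genes, is the targeted gene itself, so this count does not exclude chance for effects beyond it. For the interaction (0 genes) all 100 splits reach the real count, so they say nothing of chance. The highest other count was 1152, in a split that set wild-type libraries 7, 10 and 11 against 8, 9 and 12.

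For lists called by camera the 10 splits are again too few, with 13 lists against at most 20 in others for ethanol in wild type (7 splits as large), 10 against 13 in the knockout (4 splits), 19 against 16 for the knockout under PBS (1 split) and 11 against 23 under ethanol (9 splits). Chance is not excluded for the number of lists in the averaged ethanol effect (14, at most 24, 44 of 100 splits) or the averaged knockout effect (14, at most 26, 43 of 100). For single lists over both genotypes, chance is argued against by median for cholesterol synthesis (−0.38, next −0.33, 1 of 100) and glucocorticoid response genes (0.79, next −0.63, 1 of 100). For integrated stress response genes other splits passed the real median (0.26, highest other 0.29, 4 of 100 with the real one). That median, of a list picked from 42, leaves chance open. The means of all these lists passed the exact permutation, a like relabelling, adjusted over the 42 lists (p = 0.035).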

How the results depend on the processing

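The fit without the 3 high-muscle libraries, the muscle covariate for the correlations between effects and DESeq2 without its filter on mean counts were chosen after results were seen; all other alternatives were planned. No paired analysis was possible because the library numbers run from 1 to 12 without repeats. Where a value below differs from the reported one, the cause was not tested, except that an added fold threshold can only remove calls. In simulated data at these depths with 3 libraries per group and no muscle component, 28.4% of 1.5-fold changes were found in wild type, and depth was not varied.

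For ethanol in wild type (229 genes) DESeq2 called 731 (701 without its filter), limma-voom 138, the fit of only 2 groups 4, the muscle covariate 500, the blood cell covariate 493, the fit without the 3 high-muscle libraries 37, the threshold of 1 on log2 fold changes 50, and leaving out 1 library 35 to 320. For ethanol in the knockout (339) the same settings gave 986 and 950 (DESeq2 with and without its filter), 1677 (only 2 groups), 867 and 663 (covariates), 1342 (without the 3 libraries), 96 (threshold) and 52 to 217 (leaving out 1 library). The averaged ethanol effect (1967) went to 146 with the threshold and 1040 to 2152 without 1 library. The knockout counts of 2 went to 14 under ethanol and 215 averaged with DESeq2 (13 and 78 without its filter), the one under PBS to 3 in the fit of only 2 groups and without the 3 libraries (Slfn4 added), the one under ethanol to 3 without a low-count filter (Slc7a5 added), and the averaged one to 6 without that filter and 4 without the 3 libraries (Cat, Cd59a, Alad and Tspan33; genes named here were chosen after their values were seen). The interaction went from 0 to 1 with DESeq2, with and without its filter. Leaving out 1 library kept the knockout counts at 2 to 3 and the Cat change at −1.27 to −1.04 under PBS and −1.23 to −1.11 under ethanol.

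No gene that the naming rule took as called reversed in any setting run for it. Genes given as values that did not pass were not followed through the settings. Leaving out 1 library in turn kept 104 calls of the genes named for ethanol in wild type and lost 160, and kept 141 and lost 195 in the knockout. Of the 229, 228 were also called with the muscle covariate and 223 with DESeq2, and of the 339, 339 and 325. DESeq2 gave no adjusted p for 3 and 13 of these genes.

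Of the lists camera called, fry lost 11 of 13 for ethanol in wild type, 8 of 10 in the knockout, 19 of 19 and 10 of 11 for the knockout under PBS and ethanol and 11 of 11 for the interaction. Some list medians reversed without the 3 high-muscle libraries: for ethanol in wild type oxidative phosphorylation (0.13) and mitochondrially encoded (0.15); for the knockout under PBS muscle (1.35), platelet (−0.024), fatty acid oxidation (0.13), heat shock (0.15), lipogenesis (0.040), oxidative phosphorylation (0.16) and mitochondrially encoded (0.15); for the interaction heat shock (−0.096) and oxidative phosphorylation (−0.19). Without 1 library, the interaction median of the cell cycle list reached −0.026 (library 12) to 0.15, that of the tendon list −0.55 to 0.032 (library 6) and the osteoblast median for the knockout under ethanol −0.39 to 0.083 (library 6). Pearson r between the ethanol effects (0.486) was 0.650 with the stricter filter, 0.274 without the 3 libraries and 0.350 to 0.497 without 1 library, and between the knockout effects (0.551) 0.786, −0.0880 and 0.0941 to 0.610, with 0.171 under the muscle covariate.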

Other observations

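All tests in this part were chosen after the results were seen, and the gene lists in the next paragraphs were written from general knowledge of each pathway after some of their members had been seen among the called genes. The genes named as examples were also chosen after their values were seen.

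Genes that build ribosomes were lower after ethanol in both genotypes. Of 28 such genes all 28 had a negative ethanol effect averaged over genotypes (median −0.25 on the log2 scale, −0.32 in wild type and −0.19 in the knockout), and 17 fell and 0 rose by edgeR over all genes. Utp20, part of the complex that processes the small-subunit ribosomal RNA, fell by 0.49 (SE 0.073, adjusted p = 0.0027), Dkc1, which modifies ribosomal RNA, by 0.43 (SE 0.063, adjusted p = 0.0025) and the nucleolar protein Nop56 by 0.26 (SE 0.063, adjusted p = 0.0239). The abundant nucleolar genes Ncl (−0.14, adjusted p = 0.0635) and Npm1 (−0.060, adjusted p = 0.522) did not pass. By camera the list had adjusted p = 3.1e-14, and adjusted p = 0.0489 with an estimated correlation (unadjusted p = 0.0326). These values and those of the next lists are adjusted over the 3 lists written here, whereas the 42 fixed lists were adjusted over 42, so the results are not comparable. The hypothesis that the group as a whole is lower was tested without the 5 members called in a single genotype, which had prompted it. The other 23 were all lower, with a mean difference of −0.24 (exact permutation within genotype, two-sided p = 0.005, the smallest the 400 relabellings can give, adjusted p = 0.0075 over 3 lists). These 23 were measured in the same libraries, and genes of the list move together (estimated correlation 0.387). The test is therefore not independent of the members that prompted it. Reduced ribosome production in the shaft after binge ethanol remains a hypothesis, and ribosome production itself was not measured. The osteoblast list was lower in the same libraries (mean difference −0.82), and a changed mix of cells was not tested apart from a change within the cells.

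Genes that carry new proteins from the endoplasmic reticulum to the Golgi were lower as well. Of 32 genes of this early secretory pathway 29 had a negative averaged effect (median −0.13, −0.16 in wild type and −0.13 in the knockout), 13 fell and 0 rose. The vesicle coat gene Sec24d fell by 0.44 (SE 0.064, adjusted p = 0.0025), the coat-assembly GTPase Sar1a by 0.32 (SE 0.054, adjusted p = 0.0048) and the cargo receptor Lman1 by 0.28 (SE 0.049, adjusted p = 0.0061). The 3 with positive values, Sec24c, Tmed10 and Mcfd2, lay at 0.026 or below. The list had adjusted p = 3.5e-09 by camera, and adjusted p = 0.0392 with an estimated correlation (unadjusted p = 0.0131). Without the 2 members called in a single genotype, 27 of 30 were lower with a mean difference of −0.13 (exact permutation within genotype, two-sided p = 0.005, adjusted p = 0.0075). These 30 come from the same libraries (estimated correlation 0.118), so this test too is not independent of the members that prompted it. Osteoblasts secrete much collagen, so a lower share of active osteoblasts may account for these values, and that explanation was not tested apart from a change within the cells.

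Natural killer cell genes were higher by camera but did not pass by exact permutation. Of 16 tested, 12 had a positive averaged effect (median 0.10) and 1 rose, the activating receptor gene Klrc2 (0.50, SE 0.11, adjusted p = 0.0134). The mean difference was 0.16 (exact permutation within genotype, two-sided p = 0.145), camera gave adjusted p = 0.0208, and adjusted p = 0.341 with an estimated correlation, so a rise of the group remains open.

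The same exact permutation was run on the 42 lists fixed before the data were examined, since it uses the spread between libraries and no preset correlation. At an adjusted p of 0.035, 6 lists differed after ethanol over both genotypes by this exact permutation, all tied at p = 0.005, the smallest the relabellings can give. By camera with an estimated correlation none of the 6 passed (smallest adjusted p = 0.467). Osteoblast (mean difference −0.82), bone matrix and collagen processing (−0.44), cholesterol synthesis (−0.36) and unfolded protein response genes (−0.12) were lower, and glucocorticoid response (0.71) and integrated stress response genes (0.28) were higher. The Wnt (−0.27, adjusted p = 0.060) and osteoclast lists (0.37, adjusted p = 0.0788) came next and did not pass.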
